A study of Mus musculus with 18 samples.

How the data were processed

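Naive CD4 T cells from mice with a floxed Maf gene (Maf fl/fl), with or without the CD4Cre transgene, were cultured for 3.5 days on plate-bound antibodies against CD3 and CD28 under 3 treatments that the labels call TfhA, Tfh1 and Tfh5, per the labels' protocols. The composition of the 3 treatments is not given in the sources used here, and the names are used as they stand. Cells were sorted by flow cytometry, and 3′ mRNA libraries, which read the polyadenylated end of each transcript, were prepared from 50 ng of RNA with a Lexogen FWD kit, per the labels' protocols. The 18 libraries form 6 groups of 3, 1 per genotype label and treatment. Libraries labelled Cre-negative carry the replicate numbers 2, 4 and 5, and those labelled Cre-positive the numbers 1, 3 and 6. Nothing in the sources used here says whether a number stands for an animal, so the p-values measure the spread between these samples, which may be technical.

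Each deposited file holds expected counts per gene, made by the authors with STAR 2.7.2b and featureCounts 1.6.4 on the mouse build mm10, per the submitters' processing notes. The counts are not normalized, and 11.7% to 18.1% of the values per library, over all 27179 genes listed and values of 0 included, are not whole numbers. Some reads were therefore counted in parts and may be shared between genes. How reads were divided, and whether strand was used, is not given in the sources used here, so genes with close copies, overlapping genes and antisense genes are uncertain. The planned tests assumed whole counts, and the values were therefore rounded to whole numbers before every test. Each file lists 27179 genes by Entrez identifier, of which 25275 were named through a reference table of the assembly GRCm38.p6, the full form of mm10. The other 1904 have no name there. 2 of the unnamed identifiers, 100861531 and 19791, took 28.0% and 8.40% of the counts on average, and together 19.7% to 46.2% of a library. Total counts were 6424874 to 9236153 per library, and the smallest total without those 2 identifiers was 3555059. At this depth a group of 3 libraries with 0 counts allows up to 3 counts. Intervals and floors cover counting error only, because PCR copies are not independent molecules.

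Differential expression was tested with edgeR 4.0.16 in R 4.3.3. TMM factors, the filterByExpr filter and a robust quasi-likelihood fit with 1 mean per group were used on all 18 libraries, which left 11735 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Only 1838 of the 11735 genes had whole counts in all 18 libraries, so fractional values are not limited to the genes for which they are stated below. The median of the prior degrees of freedom was 23.3 and the common biological coefficient of variation 0.814. From this fit came the genotype effect in each treatment (Cre-positive minus Cre-negative label), the treatment contrasts within each genotype label (first named minus second named) and the differences between genotype effects. For the genotype effect over the 3 treatments, counts were summed per replicate number, which gave 3 against 3 summed libraries and 11693 tested genes. A fold is given against a floor of 3 counts over the group as "at least" where a group had 0 counts, and with a 95% counting interval where it had 1 to 3. All adjusted p-values of genes are from edgeR, and values per group are means ± SD of CPM (n = 3 libraries). CPM are the rounded counts scaled by the effective library size, which is the library size times its TMM factor. The TMM factors ran from 0.830 to 1.389, so CPM differ from counts scaled by plain library size. Fold changes are log2 values ± SE. This SE was worked back from the test, as the size of the fold change divided by the square root of the F statistic.

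25 gene lists were written from textbook knowledge: programs of T follicular helper (Tfh), Th17, Th1, Th2 and regulatory T cells, TGF-β response, coinhibitory receptors, reported c-Maf targets, IL-2/STAT5, IL-6/STAT3, interferon response, naive and memory genes, T cell receptor activation, chemokine receptors and migration, proliferation, glycolysis, cholesterol synthesis, secreted cytokines, p53 and apoptosis, and markers of B, CD8 T, NK and innate lymphoid, myeloid and dendritic, γδ T and erythroid cells. 529 of their 532 entries were matched. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of each comparison by the Benjamini-Hochberg method, and again with an estimated correlation. They were tested in the 4 genotype comparisons and the 3 treatment contrasts of libraries labelled Cre-negative. Named genes are Maf, a panel of lineage genes, up to 4 members of each list by adjusted p, and genes past the threshold with at least 10 CPM in the higher group and no overlap between the 3 libraries of each group, which chance alone gives in 10% of genes for 3 against 3. Of the latter, the 8 largest fold changes per direction were taken (10 for the effect over the 3 treatments, 5 for Cre-positive treatment contrasts and for differences of genotype effects, where overlap was allowed). Lists, tests, named-gene rule and all alternatives except 3 were fixed before the data were examined.

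On simulated counts with 50 genes changed per fold size, the test recovered 2, 13, 29 and 27 genes changed 2, 4, 8 and 16 times for the genotype effect in Tfh5, with 0 false calls among 11148 genes. For the difference between the genotype effects in Tfh5 and TfhA it recovered 2, 8, 18 and 21 with 3 false calls among 11148 genes, and for the effect over the 3 treatments 16, 32, 33 and 36 with 4 false calls among 11205 genes. For Tfh5 versus TfhA in Cre-negative cells it recovered 1, 13, 29 and 31 with 2 false calls among 11155 genes. Without any change, at most 1 of 11179 genes was called in a comparison of the 18-library fit. The effect over the 3 treatments was not simulated without change. Changed genes were drawn only from those above a minimum mean count, so recovery of genes with the fewest counts was not simulated. For the effect over the 3 treatments the same change was put into all 3, so genes that change in only 1 or 2 treatments were not covered. Alternatives were size factors of the RLE method, no count filter, DESeq2 1.42.0, limma-voom, a fit of the compared libraries alone, the replicate number as a block, and leaving out each library. For the effect over the 3 treatments, 18 libraries in 1 fit and voom with a correlation per number were tried too. Chosen after the data had been seen were a test without the 2 most abundant identifiers and thinning of all libraries to 3555059 counts outside them. A test of the identifiers with whole counts in all libraries, 3489 of them with any count, was chosen then too. No sample was left out.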

Results

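RNA from mouse CD4 T cells was measured in 18 libraries, 3 for each pair of a genotype label (CD4Cre-negative or CD4Cre-positive Maf fl/fl) and a culture treatment (TfhA, Tfh1 or Tfh5). CD4Cre deletes floxed sequences in T cells, and Maf encodes the transcription factor c-Maf, which the title of the series places between TGF-β and the choice of Tfh or Th17 fate. Total counts were 6424874 to 9236153 per library, and 10242 to 12673 genes per library had a value above 0. Pairs of replicates correlated across genes with Spearman coefficients of 0.807 to 0.916, and no 2 libraries of a group were identical. Libraries labelled Cre-negative in TfhA differed in composition on average, with 25.1% ± 7.56 (SD, n = 3) of their counts in the 2 most abundant identifiers against 38.1% ± 4.38 in Tfh1 and 40.5% ± 3.29 in Tfh5, although their replicate 2, at 33.7%, lay above Tfh1 replicate 5 at 33.1%. In libraries labelled Cre-positive this share was 36.6% ± 9.38 in TfhA, 38.3% ± 0.664 in Tfh1 and 39.8% ± 2.30 in Tfh5.

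Maf itself (mm10, chromosome 8, 115703253 to 115706894) was examined first, since it is the floxed gene. Its level ran against the genotype labels in all 18 libraries. The 9 libraries labelled Cre-negative held 17.33 Maf counts in all, with 6 of them at 0, whereas the 9 labelled Cre-positive held 12405.3. The highest library labelled Cre-negative reached 2.03 CPM and the lowest labelled Cre-positive 5.03 CPM. Among libraries labelled Cre-positive, Maf averaged 11.98 CPM ± 9.52 (SD, n = 3) in TfhA, 221 ± 34.3 in Tfh1 and 349 ± 42.0 in Tfh5. With the label Cre-negative it averaged 0.0900 ± 0.156, 0.676 ± 1.17 and 0 CPM. Over the counts of each group, Maf in libraries labelled Cre-positive was 142-fold higher in TfhA (counting interval 38.8 to 1175), 294-fold higher in Tfh1 and at least 2392-fold higher in Tfh5. In edgeR's quasi-likelihood test the difference passed the threshold in Tfh5 (adjusted p = 0.000175) and Tfh1 (log2 fold change 8.21 ± 0.96, adjusted p = 0.00123) and not in TfhA (7.01 ± 1.20, adjusted p = 0.110). Which part of Maf was floxed is not given in the sources used here. Groups are therefore named below by their labels, and every direction between genotypes is one between labels that the Maf level contradicts.

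**Figure D1:**
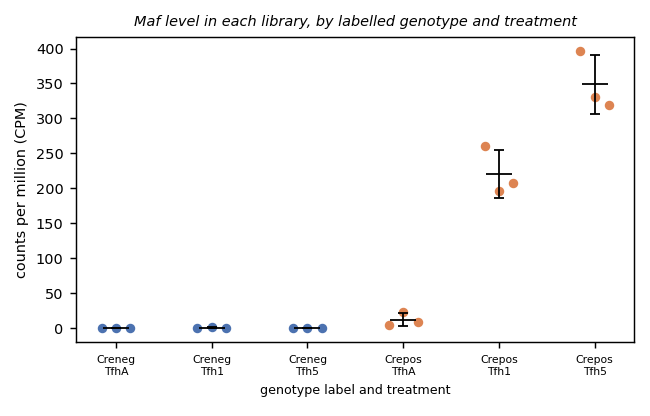
Maf level in CPM in each of the 18 libraries (dots), with the mean and SD of each group of 3, by treatment and genotype label. All 9 libraries labelled Cre-negative lie at or below 2.03 CPM, and those labelled Cre-positive lie between 5.03 CPM and the Tfh5 group, whose mean is 349 CPM.

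The genotype comparison in Tfh5 asked how cells with the 2 genotype labels differ under that treatment. Sox4, a transcription factor of the SRY-box family, rose from 17.7 CPM ± 9.22 to 482 ± 25.3 (SD, n = 3) in libraries labelled Cre-positive, which held the Maf RNA, a log2 fold change of 4.77 ± 0.63 (adjusted p = 0.000355). Klf2, a transcription factor that keeps up trafficking receptors of naive T cells, was 975-fold higher there (1039 against 1 count, counting interval 175 to 38550), and Plekho1 rose by 4.19 ± 0.57 (adjusted p = 0.000200). Il2ra, the α chain of the IL-2 receptor, fell from 764 CPM ± 115 to 239 ± 23.8 (log2 fold change -1.68 ± 0.18, adjusted p = 9.97e-08). The cytokine gene Il24 was 538-fold lower (505 against 1 count, counting interval 96.1 to 21290), and Penk, which encodes the enkephalin precursor, fell to 0.475 CPM ± 0.525 from 47.1 ± 27.1. Id2, Il21r and Hk2 fell by 1.17, 1.64 and 1.94 on the log2 scale. The values of Sox4 were fractional in 7 of 18 libraries, so that some of its reads were counted in parts and may be shared with other genes.

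Of 11735 genes, 380 passed edgeR's quasi-likelihood test in Tfh5, 140 of them higher and 240 lower with the label Cre-positive. Cre-negative replicate 5 of Tfh5 lay apart from its group on the second principal component (-119 against -45.3 and -33.2) and had the fewest genes above 0 (10242), and 287 genes were called without it. A fit of these 6 libraries alone called 80 genes, of which 77 were among the 380, and DESeq2 called 595. The Tfh list was higher (camera adjusted p = 6.99e-06, and adjusted p = 0.0126 with an estimated correlation), with 5 of 22 members higher and 1 lower, or 6 and 1 adjusted over the list alone. Its members Id3, Icos and Tox rose by 2.56 ± 0.45, 1.10 ± 0.24 and 3.49 ± 0.77 on the log2 scale. Icos encodes a costimulatory receptor needed by Tfh cells, and its level went from 54.0 CPM ± 7.46 to 116 ± 21.2. These 3 calls were lost in the fit of the 6 libraries alone. The AP-1 factor gene Batf, also on that list, was lower (log2 fold change -1.02 ± 0.27, adjusted p = 0.0244), a call lost without Cre-negative replicate 5 (adjusted p = 0.140), without Cre-positive replicate 1 (adjusted p = 0.182) and in the fit of the 6 libraries alone. Naive and memory genes were higher as a list (adjusted p = 1.07e-05, and 0.00527 as adjusted p with an estimated correlation), with 2 of 19 members higher and 1 lower, and 11 and 2 adjusted over the list alone. The member that was lower was Il7r, the IL-7 receptor gene (-1.38 ± 0.32, adjusted p = 0.00878), and that call was lost without Cre-negative replicate 2 (adjusted p = 0.116), without Cre-positive replicate 6 (adjusted p = 0.0629) and in the fit of the 6 libraries alone.

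Genes of 2 metabolic lists were lower in Tfh5. Glycolysis genes fell (camera adjusted p = 8.93e-08, and adjusted p = 0.00967 with an estimated correlation), with 7 of 21 members lower and 0 higher, or 10 lower adjusted over the list alone, and a median log2 fold change of -0.60. Hk2, the hexokinase of activated T cells, went from 134 CPM ± 5.99 to 34.8 ± 5.21 (log2 fold change -1.94 ± 0.22, adjusted p = 1.70e-07). Ldha, lactate dehydrogenase, and Pgk1, phosphoglycerate kinase, fell by 1.11 and 0.86. Cholesterol synthesis genes fell too (adjusted p = 2.05e-06, and 0.00580 as adjusted p with an estimated correlation), with 6 of 24 lower, or 10 adjusted over the list alone. Acat2, which joins acetyl-CoA units, fell by 1.13 ± 0.23 and the farnesyl diphosphate synthase gene Fdps by 1.08 ± 0.22. Ldha, Pgk1, Acat2 and Fdps lost their calls in the fit of the 6 libraries alone, whereas Hk2 kept its call in every alternative that tested it. IL-2/STAT5 genes (6 of 21 lower, 1 higher, and 9 and 1 adjusted over the list alone) and Th2 genes (2 of 11 lower, and 2 adjusted over the list alone) were lower at adjusted p = 0.00254 and 0.00996, and at adjusted p = 0.0313 and 0.0403 with an estimated correlation. The IL-2/STAT5 member that was higher was Socs1, a suppressor of cytokine signalling (log2 fold change 1.61 ± 0.43, adjusted p = 0.0277), and its call was lost without Cre-negative replicate 2 (adjusted p = 0.141) or 5 (adjusted p = 0.0906), without Cre-positive replicate 1 (adjusted p = 0.0779) or 6 (adjusted p = 0.215), with limma-voom and in the fit of the 6 libraries alone.

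3 further lists passed camera in Tfh5 only with the preset correlation. Chemokine receptor and migration genes were higher, with 2 of 22 members called and 6 adjusted over the list alone (adjusted p = 0.00996, but adjusted p = 0.0871 with an estimated correlation). Proliferation genes were lower, with 2 of 40 called and 8 adjusted over the list alone (adjusted p = 0.000481, but adjusted p = 0.0999 with an estimated correlation). B cell markers were lower, with 2 of the 4 tested called (of 16 on the list), Ebf1 and H2-Ab1, and 2 adjusted over the list alone (adjusted p = 0.00996, but adjusted p = 0.0754 with an estimated correlation). Ebf1, a transcription factor of B cell development, stood at 7.70 CPM ± 4.40 with the label Cre-negative and 0.101 ± 0.174 with the label Cre-positive, while H2-Ab1, an MHC class II gene, fell by 2.10. Th17, Th1, TGF-β response and reported c-Maf target genes were not called as lists by camera in Tfh5, at adjusted p = 0.350, 0.757, 0.886 and 0.674. Camera asks for a shift in 1 direction, and single members were called. These were 1 of 20 lower, 2 of 17 higher and 1 lower, 1 of 18 higher and 3 lower, and 1 of 13 higher. In the mixed form of the test fry, which asks for change in either direction, the adjusted p values were 7.95e-06, 6.22e-10, 1.32e-10 and 0.000264. Il17a, the Th17 cytokine gene, stood at 165 CPM ± 38.6 with the label Cre-negative and 147 ± 15.9 with the label Cre-positive (log2 fold change -0.17 ± 0.28, adjusted p = 0.900). The Tfh genes Cxcr5, Pdcd1 and Il21 had log2 differences of 2.66 ± 1.76, 0.73 ± 0.40 and 0.15 ± 0.28, at adjusted p = 0.521, 0.393 and 0.911. Bcl6, Il4, Foxp3, Ifng, Il22 and Prdm1 had too few counts to be tested.

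**Figure D2:**
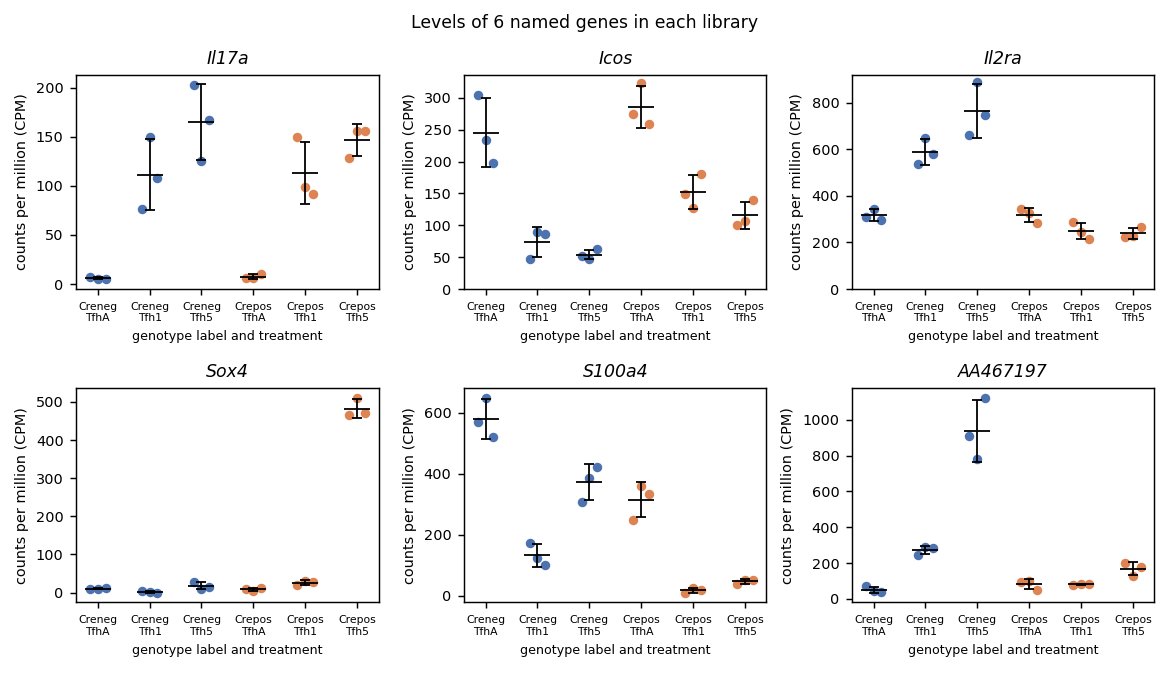
Levels in CPM of Il17a, Icos, Il2ra, Sox4, S100a4 and AA467197 in each library (dots), with the mean and SD of each group of 3, by treatment and genotype label. Sox4 stands at 482 CPM in Tfh5 libraries labelled Cre-positive and at or below 25.9 CPM in the means of the other groups, while Il17a rises from TfhA to Tfh5 with either label.

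In Tfh1 the same comparison gave a smaller set of genes in the fit of all 18 libraries. Lsp1, an actin-binding protein of leukocytes, rose from 18.7 CPM ± 5.44 to 155 ± 64.8 (SD, n = 3) in libraries labelled Cre-positive, which held the Maf RNA (log2 fold change 3.05 ± 0.34, adjusted p = 4.47e-07). Klf2 rose by 5.02 ± 0.74 and Plekho1 by 4.35 ± 0.59, and Pou2af1, a coactivator of octamer-binding factors, was at least 278-fold higher (855 against 0 counts). Il24 fell from 86.9 CPM ± 19.0 to 0.369 ± 0.639, Il2ra from 588 ± 56.2 to 250 ± 35.9 and the mean of Hk2 from 241 to 98.2. Ebf1 was at least 138-fold lower (404 against 0 counts), and the kinase gene Dclk1 was 310-fold lower (counting interval 85.5 to 2568). Cdkn1a, the cell cycle inhibitor p21, fell by 1.37 ± 0.24. In all, 100 genes passed edgeR's test, 60 higher and 40 lower, and DESeq2 called 263. A fit of these 6 libraries alone called 131 genes, 82 of them among the 100, which is more than the 80 of such a fit in Tfh5. The count was 51 without Cre-negative replicate 5, 59 without Cre-negative replicate 4, 65 without Cre-positive replicate 6 and 66 without Cre-positive replicate 1.

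Tfh genes were higher as a list in Tfh1 too (camera adjusted p = 1.82e-05, and adjusted p = 0.0278 with an estimated correlation), with 3 of 22 members called and 7 adjusted over the list alone. Naive and memory genes were higher (adjusted p = 4.84e-07, and 0.00309 as adjusted p with an estimated correlation), with 3 of 19 called, and with 6 higher and 1 lower adjusted over the list alone. Proliferation genes were lower (1 of 40 called, 8 adjusted over the list alone, adjusted p = 4.84e-07, but adjusted p = 0.0516 with an estimated correlation). Chemokine receptor genes were higher (2 of 22 called, 3 adjusted over the list alone, adjusted p = 0.0351, but adjusted p = 0.227 with an estimated correlation). B cell markers were lower (1 of 4 called, Ebf1, and 1 adjusted over the list alone, adjusted p = 0.0329, but adjusted p above 0.05 with an estimated correlation). Il17a and Il21 differed by 0.02 ± 0.28 and 0.77 ± 0.28 on the log2 scale, at adjusted p of 1 and 0.279. Apart from Maf, 32 genes were higher in both Tfh1 and Tfh5 (of 59 and 139, with 0.699 expected for independent lists, 1-sided Fisher's exact test p = 1.86e-47). Likewise 25 genes were lower in both (of 40 and 240, with 0.818 expected, p = 5.07e-33 in the same exact test), and 0 were called in opposite directions. No library is shared between these lists, but they come from 1 fit, and the same replicate numbers stand on each side in both. If a number stands for an animal, the lists are not independent. The expected numbers also treat all 11735 tested genes as equally open to a call.

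**Figure D3:**
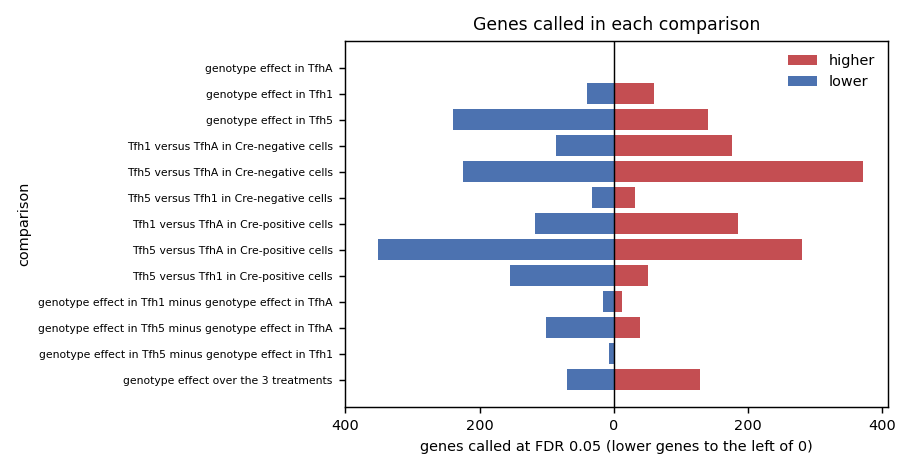
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test for each comparison, with bars to the right for genes higher and to the left for genes lower. The genotype comparison called 0 genes in TfhA, 100 in Tfh1 and 380 in Tfh5, and Tfh5 versus TfhA called 596 in libraries labelled Cre-negative.

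In TfhA the genotype labels separated few genes. Il2ra stood at 317 CPM ± 25.1 with the label Cre-negative and 317 ± 31.1 with the label Cre-positive, Icos at 245 ± 54.3 and 285 ± 33.0, and Il17a at 6.20 ± 1.30 and 7.64 ± 2.20 (SD, n = 3). edgeR called 0 of 11735 genes, with a smallest adjusted p of 0.0715, while DESeq2 called 18 and limma-voom 3. In edgeR 606 genes had an unadjusted p under 0.05, near the share of 0.05 that is expected without any change. Maf itself, with 247 against 2 counts, was not called by edgeR (adjusted p = 0.11). The 0 calls therefore do not exclude large differences in genes with few counts. Without the count filter edgeR called 23. Leaving out 1 library gave 3 genes without Cre-negative replicate 2, 1 without Cre-negative replicate 4, 2 without Cre-positive replicate 6 and 4 without Cre-positive replicate 3. 4 lists passed camera with the preset correlation, each at an adjusted p = 0.184 with an estimated correlation and with 0 members called. These were proliferation (lower, adjusted p = 0.000335), glycolysis (higher, adjusted p = 0.00237), coinhibitory receptors (higher, adjusted p = 0.0436) and chemokine receptors (higher, adjusted p = 0.0436). Adjusted over the list alone, 1 glycolysis gene and 1 coinhibitory receptor gene were higher.

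Summed over the 3 treatments, the genotype comparison gave 1 value per replicate number. Sox4 rose from 9.88 to 174 CPM on average (log2 fold change 4.14 ± 0.21, n = 3, adjusted p = 1.26e-09) in libraries labelled Cre-positive, which held the Maf RNA. Sgpp2, a phosphatase of sphingosine 1-phosphate, rose by 3.48 ± 0.37, Pou2af1 by 3.36 ± 0.25, Plekho1 by 3.17 ± 0.21, Klf2 by 2.33 ± 0.27 and the lysophosphatidic acid receptor gene Lpar6 by 1.87 ± 0.22. Several of these rises were not alike in the 3 treatments, and no gene was called in TfhA. Sox4 stood high only in Tfh5 libraries labelled Cre-positive. The genotype difference was higher than in TfhA for Klf2, Pou2af1 and Plekho1 in Tfh1, and for Klf2, Pou2af1 and Sox4 in Tfh5. AA467197 fell from 384 to 112 CPM (-1.78 ± 0.16, adjusted p = 5.28e-06), and S100a4, a calcium-binding protein of effector and memory cells, from 387 to 133 CPM (-1.54 ± 0.15, adjusted p = 1.21e-05). Sema4f, Tspan6 and Il24 fell by 1.83, 1.70 and 1.75 on the log2 scale, and Il2ra by 0.99, although the log2 difference of Il2ra in TfhA was 0.002. These falls come from Tfh1 and Tfh5 for AA467197, Sema4f and Il24, whose means in TfhA were higher with the label Cre-positive (82.4 against 51.9, 15.2 against 5.85 and 39.0 against 31.7 CPM; none called there). In all, 197 of 11693 genes passed edgeR's test, 128 higher and 69 lower. The count was 102, 106, 94, 95 and 99 without replicates 1, 2, 4, 5 and 6, and 549 with DESeq2. For the genotype effect over the 3 treatments, the balance of higher and lower calls turned with 18 libraries in 1 fit (186 higher, 226 lower) and with voom and a correlation per number (226 higher, 307 lower).

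5 lists passed camera in the summed comparison, and none of these 5 calls held with an estimated correlation. Tfh genes (3 of 22 higher, and 6 higher and 1 lower adjusted over the list alone) and naive and memory genes (3 of 19 higher, and 6 and 1 adjusted over the list alone) were higher at adjusted p = 3.93e-06 and 2.13e-05, with adjusted p = 0.0844 for each with an estimated correlation. Chemokine receptor genes were higher (3 of 22 called, 6 adjusted over the list alone, adjusted p = 0.00434), and proliferation genes (2 of 40 called, 14 adjusted over the list alone, adjusted p = 2.55e-10) and cholesterol synthesis genes (0 of 24 called, 3 adjusted over the list alone, adjusted p = 8.40e-06) were lower. For these 3 lists the adjusted p was 0.428 with an estimated correlation. Icos and Il21 differed by 0.48 ± 0.13 and 0.54 ± 0.15, at adjusted p = 0.0781 and 0.0766, and Il17a by 0.02 ± 0.16 (adjusted p = 0.985).

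Whether the genotype difference itself changed with the treatment was tested as a difference of differences. For Il2ra it was lower in Tfh1 than in TfhA by a log2 difference of -1.24 ± 0.25 (adjusted p = 0.0139) and in Tfh5 than in TfhA by -1.68 ± 0.25 (adjusted p = 8.37e-05). For Mt1, a metallothionein, and Lgals3, galectin-3, it was lower in Tfh5 than in Tfh1 by -1.78 ± 0.28 and -2.80 ± 0.42 (adjusted p = 0.000766 each). edgeR called 28 genes between Tfh1 and TfhA, 140 between Tfh5 and TfhA and 7 between Tfh5 and Tfh1. The first count was 18 without Cre-negative replicate 5 of TfhA or of Tfh1. The second count was 87 without Cre-negative replicate 5 of TfhA and 81 without Cre-positive replicate 1 of TfhA. The third was 11 and 13 without Cre-negative replicates 2 and 5 of Tfh5, and 21 and 14 without Cre-positive replicates 1 and 3 of Tfh5. DESeq2 called 63, 255 and 52 genes, and fits of the compared libraries alone called 64, 88 and 3.

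The treatments were then compared among libraries labelled Cre-negative, in which Maf was near 0. In Tfh5 against TfhA, Il17a rose from 6.20 CPM ± 1.30 to 165 ± 38.6 (SD, n = 3; log2 fold change 4.73 ± 0.33, adjusted p = 2.09e-12), and Furin, a protease that processes TGF-β, rose from 28.7 ± 6.58 to 267 ± 44.7. Pdpn, the podoplanin gene, rose from 0.568 CPM ± 0.813 to 303 ± 18.1, and the ectoenzyme gene Cd38 and the chemokine gene Ccl20 were at least 154-fold and 52.5-fold higher. Icos fell from 245 CPM ± 54.3 to 54.0 ± 7.46 (-2.19 ± 0.25, adjusted p = 1.16e-07). Dgkk, a diacylglycerol kinase gene, was at least 615-fold lower (0 against 2422 counts), Stat4, which carries IL-12 signals, fell by 4.65 ± 0.69, and Klf2 was 373-fold lower (counting interval 66.7 to 14770). Of 11735 genes, 596 were called, 372 higher and 224 lower, with 360 without Cre-negative replicate 5 of TfhA.

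Th17 genes rose as a list in Tfh5 against TfhA, with 10 of 20 members higher and 0 lower, or 12 higher adjusted over the list alone (camera adjusted p = 7.42e-25, and adjusted p = 7.02e-05 with an estimated correlation). TGF-β response genes were higher too (3 of 18 higher and 1 lower, and 4 and 2 adjusted over the list alone, adjusted p = 0.00753, and 0.0404 as adjusted p with an estimated correlation), with Pmepa1 and Skil, both feedback inhibitors of that pathway, up by 1.98 ± 0.24 and 3.37 ± 0.54. Its member Id3, an inhibitor of E proteins, fell by 4.99 ± 0.49. Reported c-Maf targets were higher (6 of 13 higher and 1 lower, and 7 and 1 adjusted over the list alone, adjusted p = 1.59e-05, and 0.00806 as adjusted p with an estimated correlation), among them Il21 (1.31 ± 0.29) and Procr (4.35 ± 0.64), whereas Icos, also on that list, fell. Th1 genes were lower (5 of 17 lower and 1 higher, and 9 and 1 adjusted over the list alone, adjusted p = 6.12e-06, and 0.00806 as adjusted p with an estimated correlation), with a median log2 fold change of -3.70, or -3.27 with genes at 0 set to their bound. Its member Cxcr6 was higher.

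Tfh genes were lower as a list in Tfh5 against TfhA (6 of 22 lower and 2 higher, and 8 and 3 adjusted over the list alone, adjusted p = 0.000317, and 0.0261 as adjusted p with an estimated correlation). Besides Icos and Id3, the receptor genes Cd200 and Btla fell by 3.34 ± 0.45 and 3.88 ± 0.72, while Il21 was higher. Naive and memory genes were lower (7 of 19 lower and 2 higher, and 10 and 2 adjusted over the list alone, adjusted p = 3.83e-07, and 0.000712 as adjusted p with an estimated correlation), with Il7r higher by 2.11 ± 0.33. T cell receptor activation genes (3 of 22 lower and 2 higher, and 4 and 2 adjusted over the list alone, adjusted p = 0.00736) and interferon response genes (3 of 29 lower, and 4 adjusted over the list alone, adjusted p = 1.59e-05) were lower, at adjusted p = 0.0278 and 0.0228 with an estimated correlation. Tnfrsf9, the costimulatory receptor 4-1BB, fell from 522 CPM to 154 (-1.76 ± 0.23), Il2ra rose by 1.27 ± 0.18, and the interferon-induced gene Oas3 was at least 141-fold lower. Proliferation genes were lower only with the preset correlation (1 of 40 called and 1 adjusted over the list alone, adjusted p = 0.00167, but adjusted p = 0.168 with an estimated correlation). The libraries labelled Cre-negative in TfhA also had a lower share of pseudogene counts, 5.55% ± 0.524 (SD, n = 3) against 8.57% ± 0.616 in Tfh5 and 7.56% ± 0.447 in Tfh1, and the share in Tfh1 was 8.64% ± 0.601 with the label Cre-positive.

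In Tfh1 against TfhA among the same libraries, Il17a rose to 111 CPM ± 36.3 (log2 fold change 4.17 ± 0.33, adjusted p = 9.14e-11), and Il21, a cytokine that helps B cells, rose by 1.62 ± 0.29. Ctla4, a coinhibitory receptor gene, rose from 77.3 CPM ± 20.6 to 312 ± 61.6, the costimulatory ligand gene Cd86 rose by 6.82 ± 0.78, and Ccl20 was at least 184-fold higher. Dgkk was at least 595-fold lower and the serpin gene Serpinb9b at least 147-fold lower, while Icos fell by 1.73 ± 0.25. edgeR called 262 genes, 176 higher and 86 lower, and 402 were called with limma-voom, 438 with DESeq2 and 566 in a fit of the 6 libraries alone. The count was 129 without Cre-negative replicate 5 of TfhA, and 166 and 147 without Cre-negative replicates 2 and 4 of Tfh1.

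Th17 genes (8 of 20 higher, and 12 adjusted over the list alone) had an adjusted p of 1.30e-24 in camera in Tfh1 against TfhA, and 8.55e-05 as adjusted p with an estimated correlation. Reported c-Maf targets (5 of 13 higher and 1 lower, and 8 and 1 adjusted over the list alone), regulatory T cell genes (4 of 16 higher, and 6 adjusted over the list alone) and coinhibitory receptors (4 of 13 higher and 1 lower, and 4 and 2 adjusted over the list alone) were higher at adjusted p = 5.12e-08, 0.000127 and 0.00189. With an estimated correlation their adjusted p values were 0.00236, 0.00559 and 0.0450. The lower members were Icos and Cd200. Th1 genes (5 of 17 lower and 1 higher, and 8 and 1 adjusted over the list alone), Tfh genes (4 of 22 lower and 2 higher, and 8 and 2 adjusted over the list alone), naive and memory genes (3 of 19 lower and 1 higher, and 5 and 1 adjusted over the list alone) and interferon response genes (0 of 29 called, and 0 adjusted over the list alone) were lower. Their adjusted p values were 1.03e-05, 0.000732, 0.00334 and 5.50e-06, and 0.0139, 0.0349, 0.0306 and 0.0271 with an estimated correlation. Against their lists, Cxcr6, Il21 and Il7r were higher, by 4.30 ± 0.52, 1.62 ± 0.29 and 1.74 ± 0.33. 3 list calls were lost: TGF-β response (3 of 18 higher and 1 lower, and 3 and 1 adjusted over the list alone, adjusted p = 0.0248, but adjusted p = 0.0709 with an estimated correlation), glycolysis (2 of 21 higher, and 3 adjusted over the list alone, adjusted p = 0.000793, but 0.0695 as adjusted p with an estimated correlation) and proliferation (1 of 40 lower, and 1 adjusted over the list alone, adjusted p = 0.00189, but 0.139 as adjusted p with an estimated correlation).

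In Tfh5 against Tfh1 with the label Cre-negative, Timp2, an inhibitor of metalloproteinases, rose from 28.3 CPM ± 6.59 to 155 ± 10.6 (SD, n = 3; log2 fold change 2.45 ± 0.29, adjusted p = 8.53e-06). The chemokine receptor gene Ccr7 fell by 1.47 ± 0.25, and the costimulatory receptor genes Tnfrsf9, Tnfrsf4 and Tnfrsf18 fell by 1.70 ± 0.23, 1.10 ± 0.19 and 1.21 ± 0.22. edgeR called 65 genes, 32 higher and 33 lower, with 35, 38 and 25 without Cre-negative replicates 2, 4 and 5 of Tfh1 and 33 without replicate 5 of Tfh5. A fit of the 6 libraries alone called 28 genes and DESeq2 211. T cell receptor activation genes (4 of 22 lower, and 6 adjusted over the list alone) and naive and memory genes (4 of 19 lower, and 4 adjusted over the list alone) were lower at adjusted p = 0.000248 each, and at 0.00813 as adjusted p with an estimated correlation. Glycolysis genes (0 of 21 called, 4 lower adjusted over the list alone) had an adjusted p of 0.000248, but adjusted p = 0.0839 with an estimated correlation. Th17 genes (1 of 20 higher, and 1 adjusted over the list alone, adjusted p = 0.0217), regulatory T cell genes (3 of 16 lower, and 4 adjusted over the list alone, adjusted p = 0.0217) and chemokine receptor genes (2 of 22 lower, and 2 adjusted over the list alone, adjusted p = 0.0490) lost their calls at adjusted p = 0.208, 0.0758 and 0.208 with an estimated correlation.

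**Figure D4:**
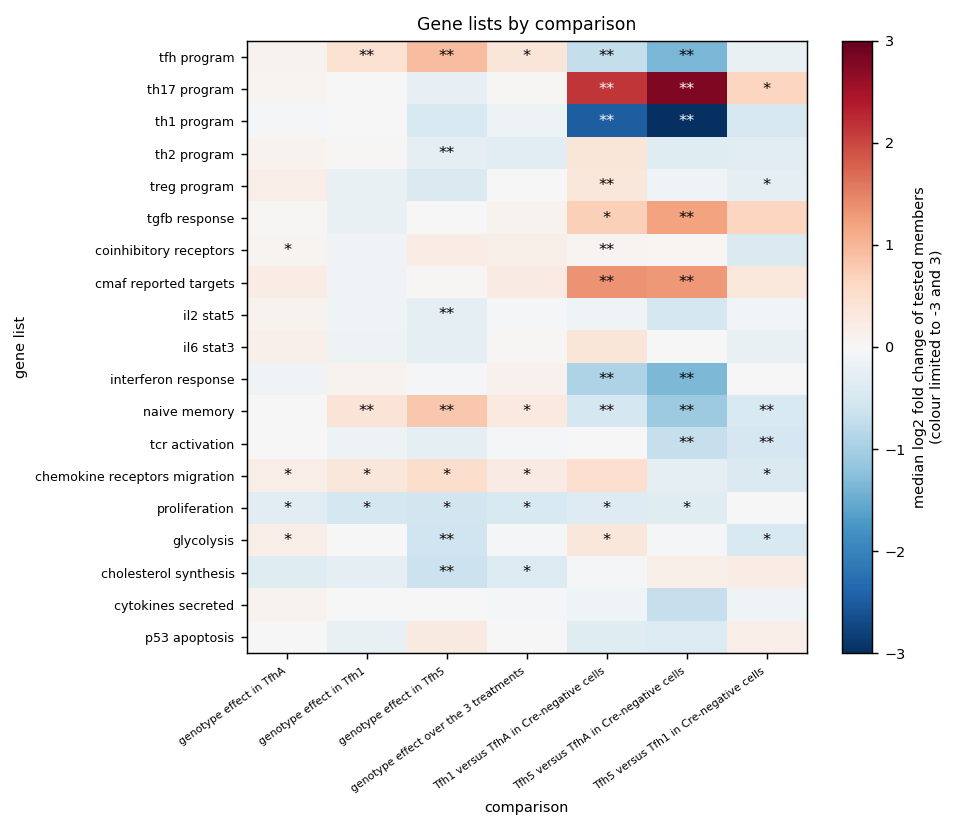
Median log2 fold change (colour, limited to -3 and 3) of 19 gene lists in 7 comparisons, with genes at 0 counts in a group set to their bound. A single star marks a camera adjusted p under 0.05 and a double star one that also holds with an estimated correlation, as for Th17 genes in Tfh5 versus TfhA at 7.02e-05.

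Among libraries labelled Cre-positive, which held the Maf RNA, Il17a rose as well, by 3.88 ± 0.32 in Tfh1 against TfhA (adjusted p = 1.68e-10) and by 4.25 ± 0.33 in Tfh5 against TfhA (adjusted p = 8.85e-12). Maf itself was 21.2-fold higher in Tfh1 and 33.3-fold higher in Tfh5 than in TfhA over the counts of each group. Ikzf3, which encodes the transcription factor Aiolos, was at least 246-fold higher in Tfh1 than in TfhA and at least 540-fold higher in Tfh5, and Tmem176b at least 124-fold and 372-fold higher. Il1r2, the decoy receptor of IL-1, was at least 211-fold lower in Tfh1 and 227-fold lower in Tfh5. Between Tfh5 and Tfh1, Sox4 rose by 4.22 ± 0.62 (adjusted p = 0.00125), and Adm, which encodes adrenomedullin, was 484-fold lower in Tfh5 (counting interval 86.5 to 19160). edgeR called 302 genes in Tfh1 against TfhA (185 higher, 117 lower), 633 in Tfh5 against TfhA (281 and 352) and 206 in Tfh5 against Tfh1 (51 and 155). DESeq2 called 588, 961 and 404 in these contrasts, and for Tfh5 versus Tfh1 in Cre-positive cells a fit of the 6 libraries alone called 115, of which 99 were among the 206. The first count was 200 without Cre-positive replicate 6 of TfhA, 170 without replicate 3 of TfhA and 185 without replicate 6 of Tfh1.

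The leading genes lie at single loci of mm10: Sox4 (Entrez 20677) on chromosome 13 from 28948919 to 28953699, Klf2 (16598) on chromosome 8 from 72319062 to 72321654, Plekho1 (67220) on chromosome 3 from 95988809 to 95999355, and Pou2af1 (18985) on chromosome 9 from 51213690 to 51240079. Il24 (93672) lies on chromosome 1 from 130882074 to 130887411, S100a4 (20198) on chromosome 3 from 90603770 to 90606045, AA467197 (433470) on chromosome 2 from 122637887 to 122641076, Dgkk (331374) on chromosome X from 6779306 to 6948363 and Timp2 (21858) on chromosome 11 from 118301061 to 118355411. All 9 are annotated as protein-coding genes.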

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

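Chosen after the counts of called genes had been seen were the tests of the Maf level, of 1 depth, of spread by treatment, without the 2 most abundant identifiers, on genes with whole counts and on genes matched by level, and the use of the planned test of differences as an explanation.

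Genes whose genotype difference changed between treatments stood out by the test of that change itself. Between Tfh1 and TfhA, edgeR called 28 such genes. The difference was higher in Tfh1 for Klf2 (adjusted p = 0.00490), Sh3bp5 (adjusted p = 0.00832), Ikzf3 (adjusted p = 0.0156), Pou2af1 (adjusted p = 0.0159) and Plekho1 (adjusted p = 0.0268). In Tfh1 it was lower for Il24 (adjusted p = 3.78e-05), Ebf1 (adjusted p = 0.00338), Cstdc4 (adjusted p = 0.00567), Dclk1 (adjusted p = 0.0268) and Uchl1 (adjusted p = 0.0288). The difference is the label Cre-positive minus the label Cre-negative throughout, and the Maf level goes against these labels. Klf2, Il24, Ebf1 and Cstdc4 passed in every alternative that tested them, though the values of Cstdc4 were fractional in 10 of 18 libraries. Sh3bp5 was lost without Cre-positive Tfh1 replicate 1 (adjusted p = 0.0800), and Ikzf3 without Cre-negative TfhA replicate 5 (0.167) or Cre-positive TfhA replicate 6 (0.0737) or 3 (0.0784), as well as with limma-voom, at 1 depth and in a fit of the 12 libraries alone. Dclk1 was lost on leaving out any of the 12 libraries (adjusted p of 0.0622 or more), and Uchl1 on leaving out any but Cre-negative Tfh1 replicate 2 (0.0540 to 0.151). Plekho1 was lost without any library but Cre-negative Tfh1 replicates 2 and 4 and Cre-positive TfhA replicate 3 (0.0793 to 0.162), and Pou2af1 without any but Cre-negative TfhA replicate 2, Cre-positive TfhA replicates 1 and 3 and Cre-positive Tfh1 replicate 3 (0.0659 to 0.0985).

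Between Tfh5 and TfhA the same test called 140 genes. The genotype difference was higher in Tfh5 for Klf2 (adjusted p = 4.32e-06), Sox4 (adjusted p = 0.00608), Adora2a (adjusted p = 0.00623), Ikzf3 (adjusted p = 0.00848) and Pou2af1 (adjusted p = 0.0445), and lower for Cstdc4 (adjusted p = 0.00236), Ermn (adjusted p = 0.00345), Plcxd1 (adjusted p = 0.0148), Dusp28 (adjusted p = 0.0176) and Pask (adjusted p = 0.0260). Ikzf3 was lost without Cre-negative TfhA replicate 5 (0.0706), with limma-voom and at 1 depth, and Dusp28 without Cre-negative TfhA replicate 2 (0.0534) or 4 (0.0600) or Cre-negative Tfh5 replicate 5 (0.0655). Pou2af1 was lost without any of the 12 libraries but Cre-negative Tfh5 replicates 2 and 5 and Cre-positive TfhA replicate 1 (0.0583 to 0.153), and Pask without any but Cre-negative Tfh5 replicates 2 and 5 and Cre-positive TfhA replicate 3 (0.0521 to 0.0744). Plcxd1 was lost with limma-voom, with the block and in a fit of the 12 libraries alone. Between Tfh5 and Tfh1 the test called 7 genes, among them Lgals3, Mt1 and Fam162a (adjusted p = 0.000766 each), Ly6a (adjusted p = 0.0168) and Tgm2 (adjusted p = 0.0203), all lower in Tfh5. Lgals3 was lost with limma-voom. Ly6a was lost without Cre-negative Tfh1 replicate 2 (0.0787) or 5 (0.0878) or Cre-positive Tfh1 replicate 1 (0.0610), and Tgm2 without Cre-negative Tfh1 replicate 2 (0.0741) or 4 (0.0837), Cre-positive Tfh1 replicate 3 (0.0728) or 1 (0.0889) or Cre-positive Tfh5 replicate 6 (0.0571). The values of Ly6a and Tgm2 were fractional in 17 and 11 of 18 libraries, so both are uncertain. Most tested genes had fractional values in some library, and the other genes named here may be affected as well. With groups of 3, no test of single libraries that lie far from their group was run.

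Maf was near 0 with the label Cre-negative and high with the label Cre-positive, the opposite of what deletion by CD4Cre would give. Reads left from a part of Maf outside the deleted segment do not account for this, since the undeleted gene would give those reads too, and the 9 libraries labelled Cre-negative held 0.140% of the Maf counts of the other 9. An exchange of the 2 labels may be the cause, but that all 18 libraries lie on the side of the other label only restates the pattern. It cannot be told apart from right labels with Maf RNA raised in cells that lack the protein, because Maf was higher with the label Cre-positive in all 3 treatments and no library here gives the undeleted level by another measure.

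The genotype comparison called 380 genes in Tfh5, 100 in Tfh1 and 0 in TfhA. In fits of the 6 libraries of each treatment alone these counts were 80, 131 and 0, so the order of Tfh5 and Tfh1 was not kept. Lower depth in TfhA is argued against, since its libraries were on average not shallower than those of Tfh5 outside the 2 most abundant identifiers, and 379 genes were still called in Tfh5 after its libraries had been thinned to the depth of the shallowest TfhA library. A larger spread in TfhA is argued against too, since the common coefficient of variation of its 6 libraries was 0.610, below 0.681 in Tfh1 and 0.730 in Tfh5. By group of 3 it was lowest in TfhA within each label, but differed between labels. The TfhA group labelled Cre-positive (0.821, against 0.611 with the label Cre-negative) lay above the Tfh1 group labelled Cre-negative (0.769). A genotype effect that differs between treatments is a hypothesis that would give the 140 genes called for the difference between Tfh5 and TfhA. Those calls come from the same fit as the counts above. Maf itself, over the counts of each group labelled Cre-positive, stood at 10.4 CPM in TfhA, 220.1 in Tfh1 and 346.4 in Tfh5. Whether the smaller Maf difference in CPM goes with the 0 calls in TfhA was not tested. Cells of another make-up after sorting stay open. B cell markers were lower as a list in Tfh5 (camera adjusted p = 0.00996) but not past the threshold with an estimated correlation (adjusted p = 0.0754). Only 4 of 16 were tested, and the rest had too few counts or no match. The 2 called, Ebf1 and H2-Ab1, cannot tell other cells from a change within the same cells.

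Tfh5 against TfhA called 596 genes with the label Cre-negative, where library composition differed as well. With all libraries at 1 depth 623 genes were called, so depth does not account for the calls, whereas the 598 called without the 2 most abundant identifiers decide nothing, since leaving these out moved no comparison by more than 1.5 times. Reads shared between genes and pseudogenes could not be excluded: 28 of 1838 genes with whole counts were called, 1.52% against 5.08% of all genes, a ratio of 0.300 that met the value set beforehand for this cause. That ratio was then judged void because genes with whole counts had a median of 3.69 CPM against 15.4 CPM for the rest, and against other genes of the same level (1.20% called) the ratio was 1.27. With the label Cre-positive the share of the 2 identifiers was 36.6% ± 9.38 (SD, n = 3) in TfhA and 39.8% ± 2.30 in Tfh5. Tfh5 against TfhA still called 633 genes there, which argues against that share as the cause in those libraries. Whether these are the same genes as the 596 was not tested. The treatment itself, as named in the labels, remains open alongside shared reads and, with the label Cre-negative, composition.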

How the results depend on the processing

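The tests without the 2 most abundant identifiers, at 1 depth and on genes with whole counts were chosen after the main counts of called genes had been seen, and the other alternatives before the data. Of 210 counts of called genes under alternatives, over 13 comparisons, 129 stayed within 1.5 times the main count, 40 rose above that range and 41 fell below it. Of 6229 values for 443 named genes, 5474 kept their side of the threshold, 37 became called and 718 lost the call, and for 161 list results these numbers were 344, 11 and 36 of 391. No direction was reversed where the main or the other value was called; list tests by fry and with an estimated correlation were not compared. The causes of the changes below were not tested, except that fewer genes or libraries enter some alternatives by construction. Depth limits low genes, since the shallowest library held 3555059 counts outside the 2 most abundant identifiers.

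Without a count filter the calls were 23 for the genotype effect in TfhA, 168 in Tfh1, 455 for the genotype effect over the 3 treatments, 232 for Tfh5 versus Tfh1 in Cre-negative cells, 314 for Tfh5 versus Tfh1 in Cre-positive cells, and 61, 235 and 45 for the genotype effect in Tfh1 minus genotype effect in TfhA, the genotype effect in Tfh5 minus genotype effect in TfhA and the genotype effect in Tfh5 minus genotype effect in Tfh1. DESeq2 gave 18, 263 and 595 for the genotype effect in TfhA, genotype effect in Tfh1 and genotype effect in Tfh5, 549 over the 3 treatments, 438 for Tfh1 versus TfhA in Cre-negative cells, 211 for Tfh5 versus Tfh1 in Cre-negative cells, 588, 961 and 404 for Tfh1 versus TfhA in Cre-positive cells, Tfh5 versus TfhA in Cre-positive cells and Tfh5 versus Tfh1 in Cre-positive cells (the last with 145 higher and 259 lower), and 63, 255 and 52 for the 3 differences. limma-voom gave 3 for the genotype effect in TfhA, 402 for Tfh1 versus TfhA in Cre-negative cells, 556 for Tfh1 versus TfhA in Cre-positive cells and 1019 for Tfh5 versus TfhA in Cre-positive cells. RLE factors gave 1 for the genotype effect in TfhA. With the libraries of a comparison alone the calls were 80 for the genotype effect in Tfh5, 566 for Tfh1 versus TfhA in Cre-negative cells, 28 and 115 for Tfh5 versus Tfh1 in Cre-negative cells and Tfh5 versus Tfh1 in Cre-positive cells, and 64, 88 and 3 for the differences.

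For the genotype effect over the 3 treatments, voom with a correlation per number (-0.0106) called 533 genes, and 18 libraries in 1 fit 412, of which 186 were higher and 226 lower against 128 and 69. At 1 depth the genotype effect in TfhA gave 1 call and the genotype effect in Tfh5 379. Genes with whole counts (1831 tested, 1804 for the effect over the 3 treatments) gave 1, 7 and 13 calls for the genotype effect in TfhA, genotype effect in Tfh1 and genotype effect in Tfh5, 5 over the 3 treatments, 18, 24 and 5 for Tfh1 versus TfhA in Cre-negative cells, Tfh5 versus TfhA in Cre-negative cells and Tfh5 versus Tfh1 in Cre-negative cells, 20, 37 and 13 for the same contrasts in Cre-positive cells, and 3, 11 and 3 for the differences. Of the 380 genes called for the genotype effect in Tfh5, 363 were shared with RLE factors, 354 without a filter, 380 with DESeq2, 281 with limma-voom, 77 with the 6 libraries alone and 357 at 1 depth. In Tfh5 versus TfhA in Cre-negative cells the median log2 fold change of all genes was -0.09, and -0.20 with limma-voom and -0.19 with the block.

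Leaving out 1 library gave 0 to 4 calls for the genotype effect in TfhA, 51 to 99 for the genotype effect in Tfh1, 258 to 387 for the genotype effect in Tfh5 and 94 to 166 for the genotype effect over the 3 treatments. The ranges were 129 to 202, 360 to 555 and 25 to 94 for Tfh1 versus TfhA in Cre-negative cells, Tfh5 versus TfhA in Cre-negative cells and Tfh5 versus Tfh1 in Cre-negative cells, and 170 to 282, 448 to 543 and 145 to 192 for Tfh1 versus TfhA in Cre-positive cells, Tfh5 versus TfhA in Cre-positive cells and Tfh5 versus Tfh1 in Cre-positive cells. For the genotype effect in Tfh1 minus genotype effect in TfhA, the genotype effect in Tfh5 minus genotype effect in TfhA and the genotype effect in Tfh5 minus genotype effect in Tfh1 they were 18 to 27, 81 to 164 and 5 to 21.

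The replicate numbers are shared across treatments within a genotype label, so the number was tried as a block. Samples of 1 number did not deviate together: over 18 pairs the correlation of their deviations ran from -0.037 to 0.066, and in 9 the own number correlated best. With the block the calls were 282, 595 and 63 for Tfh1 versus TfhA, Tfh5 versus TfhA and Tfh5 versus Tfh1 in Cre-negative cells, 314, 604 and 194 for the same contrasts in Cre-positive cells, and 33, 135 and 16 for the genotype effect in Tfh1 minus genotype effect in TfhA, the genotype effect in Tfh5 minus genotype effect in TfhA and the genotype effect in Tfh5 minus genotype effect in Tfh1. In Tfh5 versus Tfh1 in Cre-negative cells the block ended the list calls of Th17, regulatory T cell and chemokine receptor genes, at adjusted p = 0.0973, 0.0983 and 0.0973. Among named genes it ended the calls of Pask, Plcxd1, Pou2af1 and Uchl1 for the differences, of Dcn, Pou2af1, Prr5l, Skil and Tmem176a in Tfh1 versus TfhA, of Aoc1, Irf4, Nkg7, Serpinb6b and Slamf6 in Tfh5 versus TfhA and of Klf2, Lif, Slamf1, Sox4, St6gal1 and Tmem176b in Tfh5 versus Tfh1 with the label Cre-negative, and of Tff1 in Tfh5 versus Tfh1 with the label Cre-positive. It ended no other call of a gene or list named in the text.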

Other observations

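Of the tests in this part, that of the hypoxia list was chosen, and the list written, after the glycolysis result and some of its members had been seen.

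Several lists gave no call in any of the 7 comparisons in which they were tested by camera. The smallest adjusted p was 0.144 for IL-6/STAT3 genes (Tfh1 versus TfhA in Cre-negative cells), 0.128 for secreted cytokines (genotype effect in Tfh1) and 0.350 for p53 and apoptosis genes (genotype effect in Tfh5). Markers of other cell types reached 0.109 for CD8 T cells (genotype effect in Tfh5), 0.0754 for NK and innate lymphoid cells (Tfh1 versus TfhA in Cre-negative cells) and 0.166 for myeloid and dendritic cells (Tfh5 versus TfhA in Cre-negative cells). The directional test fry asks another question, whether a list shifted in 1 direction and not whether it shifted more than other genes. It called 3 of these lists, at adjusted p = 0.0472 for p53 and apoptosis genes (Tfh5 versus TfhA in Cre-negative cells), 0.0274 for CD8 T cell markers and 0.0149 for NK and innate lymphoid markers in the comparisons above. In the mixed form of fry, which asks for change in either direction, CD8 T and NK markers had adjusted p = 0.514 and 0.216 there. That form called IL-6/STAT3 genes (genotype effect in Tfh5, adjusted p = 6.22e-10) and secreted cytokines (genotype effect in Tfh1, adjusted p = 8.07e-12). With 4, 5 and 3 tested members these marker lists are short, and γδ T cell and erythroid markers had too few tested members for a test. Klrk1, the NKG2D gene and 1 of the 4 CD8 T cell markers tested, had 0.0361 as adjusted p in edgeR for the genotype comparison in Tfh5, lower with the label Cre-positive.

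Glycolysis genes were lower in Tfh5 libraries labelled Cre-positive, and 1 hypothesis is that they are part of a wider drop of genes induced by low oxygen. A list of 26 such genes without the glycolysis list, of which 25 were tested, was lower in that comparison (camera p = 4.46e-10, and p = 0.00183 with an estimated correlation), with a median log2 fold change of -0.75. Ero1a, Ndrg1, Vegfa, Ak4, Adm, Bnip3, Ankrd37 and Higd1a were lower over all genes, 8 of 25, and 12 were lower and 1 higher adjusted over the list alone. The list was not lower in Tfh1 (p = 0.541), and in TfhA it was higher (p = 0.00165, but p = 0.0746 with an estimated correlation). With the label Cre-negative it was higher in Tfh1 against TfhA (p = 4.94e-07, and p = 0.00890 with an estimated correlation, 5 members called) and lower in Tfh5 against Tfh1 (p = 2.88e-09, and p = 0.00229 with an estimated correlation, 0 called), with p = 0.783 in Tfh5 against TfhA. These 6 p-values are not adjusted. Oxygen or cell density in the culture wells may differ between groups in a way that no label records.

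Other splits of the 6 libraries of a comparison into 3 against 3 number 10 with the real split, too few for a share under 0.05. For the effect over the 3 treatments the 6 summed libraries were split. For the differences between genotype effects the 6 replicate numbers were split, and all libraries of a number in the compared treatments moved together. For the genotype effect in TfhA all 10 splits called as many genes as the real one, which called 0, and the highest other called 1. That outcome was fixed beforehand, since no split can call fewer than 0, so it says nothing about this grouping. In each of the other comparisons only 1 split, the real one, reached the real count. For the genotype effect in Tfh1 the real count was 100 and the highest other 1, in Tfh5 380 and 7, and over the 3 treatments 197 and 0. With the label Cre-negative, the real count and highest other were 262 and 0 for Tfh1 versus TfhA, 596 and 1 for Tfh5 versus TfhA and 65 and 1 for Tfh5 versus Tfh1. With the label Cre-positive they were 302 and 1, 633 and 1, and 206 and 2. For the differences between genotype effects they were 28 and 1 (Tfh1 and TfhA), 140 and 1 (Tfh5 and TfhA) and 7 and 1 (Tfh5 and Tfh1).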
